A study of Homo sapiens with 60 samples.

How the data were processed

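RNA sequencing of HT29 cells was analysed from the gene table that the authors deposited, with 60 libraries in 20 groups of 3. The labels give a treatment of 24 h with 0.1% DMSO, wortmannin at 10 µM or 1 of 6 hot-water extracts at 20, 100 or 500 µg/mL. The series text instead gives 2% DMSO, and doses set from the IC20 for extracts whose IC20 was under 500 µg/mL. The labels were used. The deposited values are expected counts per gene from RSEM, and 10.9% of them are not whole numbers. Per the submitters' processing notes, reads of 100 bases from both ends of each fragment, from a directional library kit, were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to hg38 with STAR 2.7.3a and counted with RSEM 1.3.3. The annotation release and the strand setting are not given in the sources used here.

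All 60 columns were matched to samples by their labels, and 0 columns were left over. The table held 60675 Ensembl genes, of which 56558 had a current symbol and 3620 had none. Among tested genes 99.3% had a symbol. Libraries held from 18.1 to 30.8 M counts (median 24.2 M), from 14688 to 16093 genes with at least 10 counts, and from 7.41% to 11.5% mitochondrial counts. Variance between replicates was 2.07 to 18.1 times that of sampling (median 3.89) over the 60 replicate pairs, and 0 columns were identical.

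Expected counts were rounded and analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 16729, and libraries were scaled by TMM. One model with 20 group means (40 residual degrees of freedom) was fitted, and edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment was used for each contrast. A gene was called at an adjusted p under 0.05 without a minimum fold change. There were 19 contrasts with vehicle, 6 of the high with the low dose of an extract, and 1 test with 5 degrees of freedom of whether the 6 high-minus-low changes were equal. Log2 fold changes are given with their standard error, and CPM, counts scaled to library size, are on the TMM scale as mean ± SD of 3 libraries.

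Gene lists were written down from general knowledge, 40 in number. The 34 with at least 5 tested members were tested with fry, which asks whether the genes of a list move on balance in 1 direction, not whether they move more than other genes. Each call was compared with camera with an estimated correlation between genes, given in the text as "with an estimated correlation". That test differs from fry in 2 ways, since it also compares the list with the other genes. Counts of list members that rose or fell use the adjustment over all tested genes, and a second count is adjusted over the list alone. Similarity was described by Pearson's r between the log2 fold changes of the extracts (15 pairs) and of each extract with wortmannin (6 pairs), and by the numbers of genes called in both with those expected from independent calls.

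The genes named in the text follow a rule. In the main comparisons, wortmannin and the high doses against vehicle, they are the 6 highest and 6 lowest log2 fold changes among called genes. In the other contrasts they are 3 and 3. A gene had to have a mean of at least 1 log2 CPM and all 3 treated libraries above or below all 3 reference libraries. Clone names, antisense transcripts and pseudogenes were left out. Up to 3 genes of each called list and 40 marker genes of known pathways, 39 of them tested, were added.

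Groups, contrasts, tests, lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives were RLE scaling, DESeq2 1.42.0 with its own size factors and filter (its dispersion trend was a local regression, which it put in place of the parametric one), no low-count filter, the replicate number as a block, a fit of only the 2 groups compared, counts that were not rounded, a 2-fold minimum and leaving out each library in turn. A correction for GC content, by an offset that removes each library's smooth trend of log2 CPM against GC content, was added after names of genes called at low doses had been seen.

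The procedure was tested on simulated data drawn from the means and library sizes of the real samples, with 200 genes changed. For the contrast of Polygalae high with vehicle, on 16568 simulated genes, 74%, 72%, 90% and 98% of genes changed 1.25, 1.5, 2 and 4 times were recovered, with 7 false calls. For Polygalae high minus low the shares were 70%, 76%, 90% and 98% with 12 false calls, and for the test that the 6 changes were equal 50%, 62%, 82% and 98% with 15. For the contrast with vehicle, among genes of at least 10 CPM the shares were 92.5%, 96.9%, 100% and 100%. A contrast without changes gave 0 calls, a simulated GC trend gave 3747 calls before and 0 after the correction, and fry called 0 of 20 unchanged lists. Genes were simulated independently of each other. These checks therefore cannot show how the calls or fry behave when genes are correlated or whole libraries shift. The simulated GC trend was smooth, as the correction assumes, so its removal says little about other trends. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Some genes that the naming rule chose are not reported here. Reads and alignments were not analysed here.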

Results

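RNA was sequenced from HT29 cells, an established human colorectal adenocarcinoma line, after 24 h with a vehicle, a kinase inhibitor or a water extract of a medicinal plant. The 60 libraries formed 20 groups of 3: a DMSO vehicle, wortmannin at 10 µM as the positive control, and 6 extracts at 20, 100 and 500 µg/mL, called here the low, medium and high dose. These are the doses in the sample labels. The series text says that for extracts with an IC20 under 500 µg/mL the IC20 and its dilutions to 1/5 and 1/25 were used, and which extracts this concerns is not given in the sources used here. It also gives 2% DMSO for the vehicle where the labels give 0.1%. The extracts were made from Liriopis seu Ophiopogonis Tuber (Liriopis), Schisandrae Fructus (Schisandrae), Longan Arillus (Longan), Zizyphi Semen (Zizyphi), Polygalae Radix (Polygalae) and Aucklandiae Radix (Aucklandiae). The series describes its aim as recording what herbal medicines do to cells as transcriptome data. Expected counts were given for 60675 Ensembl genes. Their total ran from 18.1 to 30.8 M per library, with a median of 24.2 M, and 16729 genes had enough counts to be tested.

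Each comparison with vehicle asked which transcripts a treatment changed, and wortmannin, which blocks the phosphoinositide 3-kinases between growth factor receptors and AKT, gave the scale. Wortmannin changed 5449 genes, 2634 higher and 2815 lower. At the high dose Polygalae changed 3601 genes, Aucklandiae 3389, Zizyphi 752, Schisandrae 237, Longan 230 and Liriopis 0. The sources do not say whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples. Library numbers put vehicle, wortmannin and the extracts in different sets, so a difference from vehicle cannot be told apart from a difference between sets. The labels also name DMSO for the vehicle libraries only. A difference from vehicle can therefore not be told apart from one in solvent either. The comparison of the high with the low dose of an extract lies within 1 set and does not use the vehicle libraries.

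**Figure D1:**
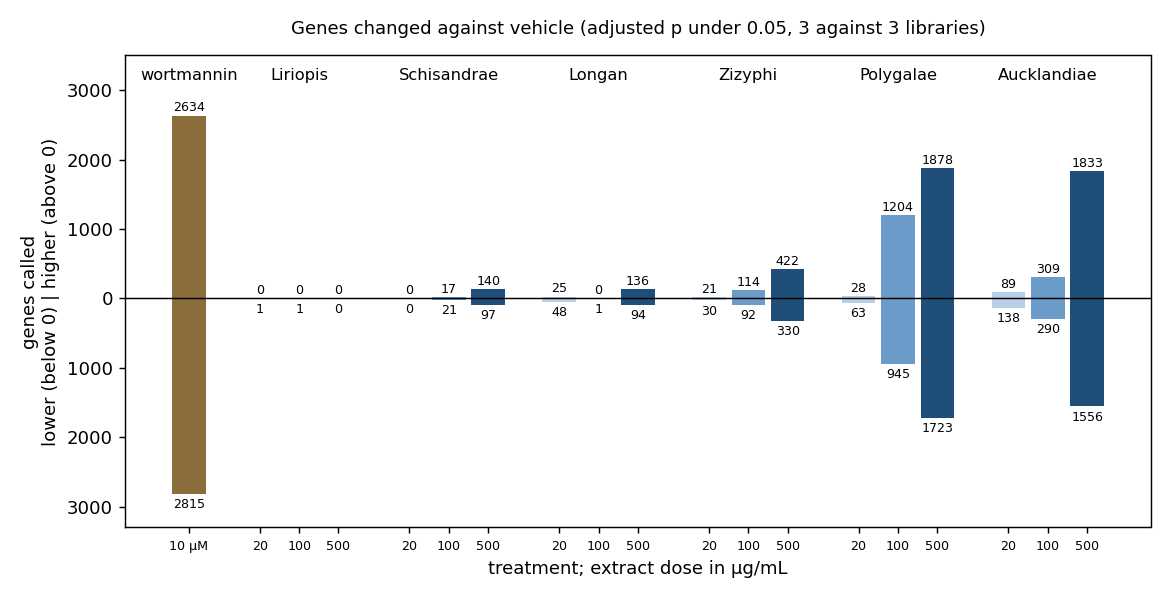
Number of genes with an adjusted p under 0.05 against vehicle (y axis; higher above 0, lower below 0) for wortmannin and each extract dose in µg/mL (x axis), 3 against 3 libraries. Polygalae and Aucklandiae changed 3601 and 3389 genes at 500 µg/mL, and Liriopis changed 0.

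Wortmannin lowered genes of cell division and raised interferon-stimulated genes. All 32 tested genes of the mitosis list fell. Interferon-stimulated genes rose in 28 of 29 cases, although no interferon was added according to the labels. Transcripts of FOXO factors' targets, which active AKT holds down, rose, while amino acid synthesis, protein folding and ribosome biogenesis genes fell. 

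Among interferon-stimulated genes, OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723 on GRCh38), which makes the activator of RNase L, rose by a log2 fold change of 2.01 ± 0.25 (SE), from 1.80 ± 0.355 to 7.16 ± 1.04 CPM (counts scaled to library size, mean ± SD, n = 3), with adjusted p = 9.1e-09. MX1, an antiviral GTPase, rose by 1.68 ± 0.14 and IFI27 by 1.66 ± 0.13. IFI6 rose by 1.62, the RNA-binding IFIT1 by 1.31, OAS1 by 1.04 and the GTPase GBP2 by 0.78. The median log2 fold change of the 29 genes was 0.78, all 29 rose when adjusted over the list alone, and fry gave the list an adjusted p of 1.3e-19 (1.73e-05 with an estimated correlation). BAIAP3 (1.46) and the junction protein CGNL1 (1.43) rose outside the list.

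The median of the mitosis list was -0.80, with adjusted p = 1.5e-38 (9.98e-19 with an estimated correlation), and all 32 genes fell when adjusted over the list alone. Cyclin B1, CCNB1 (ENSG00000134057, chromosome 5, 69167010 to 69178245), fell from 175 ± 1.98 to 82.5 ± 3.81 CPM, a log2 fold change of -1.08 ± 0.03 with adjusted p = 1.7e-35. The kinetochore motor CENPE changed by -1.18 ± 0.22, securin (PTTG1) by -1.06, the kinase PLK1 by -1.05, DLGAP5 by -1.01 and the kinase AURKA by -0.99. Outside the list PRR11 changed by -1.01. The proliferation marker MKI67 changed by -0.81 ± 0.06. Of the replication and E2F list 13 of 32 genes fell and 4 rose, also when adjusted over the list alone, among them the ribonucleotide reductase genes RRM1 (-0.44) and RRM2 (-0.26) and thymidylate synthase TYMS (-0.35). That list had adjusted p = 4e-06, and adjusted p = 0.295 with an estimated correlation.

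FOXO targets rose in 11 of 21 cases and fell in 1, with the same counts when adjusted over the list alone (adjusted p = 3.85e-14, and 0.00535 with an estimated correlation). TXNIP, which restrains glucose uptake, rose by 0.85 ± 0.05, the insulin receptor INSR by 0.59, ERBB3 by 0.25 and the adaptor IRS2 by 0.64. ATF4 targets fell in 16 of 29 cases and in 18 when adjusted over the list alone (adjusted p = 8.52e-22, and 9.1e-06 with an estimated correlation). They included asparagine synthetase ASNS (-0.63 ± 0.05), GARS1 (-0.35) and the leucine transporter SLC7A5 (-0.37). Chaperones of the endoplasmic reticulum fell, with HSP90B1 at -0.58, HSPA5 at -0.39 and PDIA4 at -0.36 (12 of 21 genes of that list, and 13 when adjusted over the list alone). Heat shock genes HSP90AA1 (-0.44), HSPD1 (-0.37) and STIP1 (-0.31) were among the 16 of 19 that fell by both adjustments. Of 30 MYC targets and ribosome biogenesis genes 24 fell, and 27 when adjusted over the list alone, LDHA by 0.42 and DDX21 by 0.28 on the log2 scale.

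Hypoxia-responsive genes rose in 11 of 23 cases and fell in 1 by both adjustments, P4HA2 rising by 0.51 and PDK1 by 0.33 (list adjusted p = 3.42e-12, and 0.0148 with an estimated correlation). The metastasis-linked gene NDRG1 of that list rose by 1.12 ± 0.11, with adjusted p = 5.2e-12. Its p was 0.052 in a fit of the 6 libraries alone and ran from 5.5e-61 to 0.052 over 7 alternatives. The growth factor VEGFA was the 1 that fell (-0.15 ± 0.05, adjusted p = 0.011), a call lost without vehicle replicate 2 (0.14) or wortmannin replicate 1 (0.10) or 2 (0.052). Enterocyte genes rose in 9 of 18 cases and fell in 1 by both adjustments, the microvillus protein villin (VIL1) by 0.48 and LGALS4 by 0.24. Among secretory genes lysozyme (LYZ) rose by 0.48 to 2060 ± 35.5 CPM, BCAS1 by 0.48 and TFF3 by 0.78. Of the WNT list LGR5 rose by 0.51 and ASCL2 by 0.68, which were chosen by the naming rule and do not stand for stem cell genes as a group. The secretory list had adjusted p = 7.77e-08 and adjusted p = 0.106 with an estimated correlation. The WNT list had adjusted p = 7.45e-10 and adjusted p = 0.0579 with an estimated correlation. The iron exporter SLC40A1 rose by 0.61 and the reductase AKR1C1 by 0.85. GCLM and SLC7A11, from the same antioxidant list as AKR1C1, were called lower by edgeR (adjusted p = 0.00045 and 0.02). Both calls were lost in a fit of the 6 libraries alone (0.23 and 0.42). That of SLC7A11 was also lost without vehicle replicate 2 or 3 or wortmannin replicate 1.

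Liriopis at the high dose changed no gene past the threshold. edgeR's quasi-likelihood test called 0 genes against vehicle, with 1271 at an unadjusted p under 0.05. DESeq2 called 26, a fit without the low-count filter 158, a replicate block 16, a fit of the 6 libraries 3 and the GC correction 1. The gene with a call at the low and the medium dose was MT-RNR1 (ENSG00000211459, mitochondrial chromosome, 648 to 1601), the 12S rRNA of mitochondrial ribosomes. It was lower by 0.45 ± 0.07 on the log2 scale at the low dose, at 1260 ± 36 against 1720 ± 40.4 CPM in vehicle. For the low and the medium dose the count of 1 became 286 and 157 without the low-count filter, 12 and 2 with DESeq2, 7 and 8 with a replicate block and 21 and 4 in a fit of the 6 libraries. At the medium dose the log2 fold change of MT-RNR1 was -0.39 ± 0.07 with adjusted p = 0.017, from 8.4e-29 to 0.48 over 7 alternatives. That call was lost without any vehicle library (0.17 without replicate 1, 0.10 without replicate 2, 0.057 without replicate 3), and without Liriopis medium replicate 2 (0.31) or 3 (0.41). fry called 0 of 34 lists at the high dose, with 5 at an unadjusted p under 0.05, and camera with an estimated correlation also called 0. The call of 0 genes rose to 5 without vehicle replicate 3.

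Schisandrae at the high dose raised antioxidant genes that NRF2 controls. The lists of cholesterol synthesis and goblet cell genes shifted lower on balance, with under 0.3 of their members past the threshold. NRF2 is the factor that reacts to electrophiles by switching on glutathione and quinone metabolism. The changes were small: of 237 genes called (140 higher, 97 lower), 3 changed at least 2-fold. 

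NRF2 targets rose in 19 of 30 cases, and in 26 when adjusted over the list alone, with a median of 0.25 (adjusted p = 1.26e-18, and 3.78e-14 with an estimated correlation). The aldo-keto reductase AKR1C2 (ENSG00000151632, chromosome 10, 4987400 to 5018031) rose by 0.69 ± 0.07, from 16.8 ± 1.36 to 27.1 ± 1.79 CPM, with adjusted p = 2.2e-10. Heme oxygenase HMOX1 rose by 0.57 ± 0.07 (2.1e-07), AKR1B10 by 0.55 ± 0.05 (1.9e-12), AKR1C1 by 0.50 and the quinone reductase NQO1 by 0.29. AKR1C1 and AKR1C2 are close paralogs, between which the count program divides shared reads. GCLM, which limits glutathione synthesis, rose by 0.62 ± 0.06, and the cystine importer SLC7A11 by 0.56 ± 0.08. In a fit of these 6 libraries alone their adjusted p rose from 2.4e-10 to 0.093 and from 4.2e-05 to 0.29. Over 7 alternatives they ran from 2e-39 to 0.093 and from 5.4e-44 to 0.29, and the vehicle libraries themselves varied (122 ± 23.9 CPM for SLC7A11). Aryl hydrocarbon receptor targets, which metabolise planar aromatic compounds, rose in 6 of 9 cases by both adjustments, including the aldehyde dehydrogenase ALDH3A1 (0.54 ± 0.06) and CYP1B1 (0.36 ± 0.05). Among conjugating enzymes UGT1A10 (0.18) and UGT1A1 (0.24) rose. Their xenobiotic list was called as higher (adjusted p = 0.00848, and adjusted p = 0.0789 with an estimated correlation) with a median of 0.0409 and a mean of -0.013.

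Cholesterol synthesis genes fell in 7 of 26 cases, and in 10 when adjusted over the list alone, by little: the median was -0.08 (adjusted p = 3.54e-07, and 0.000305 with an estimated correlation). INSIG1, which holds back SREBP processing, fell by 0.16 ± 0.03 on the log2 scale. Goblet cell genes fell in 5 of 22 cases (8 fell and 1 rose when adjusted over the list alone), with a median of -0.24 (adjusted p = 7.73e-08, and 4.65e-05 with an estimated correlation). AGR2, a disulfide isomerase needed for mucin folding, changed by -0.24 ± 0.03, the membrane mucin MUC13 by -0.24 ± 0.04 and REG4 by -0.30 ± 0.06. Falls outside these lists included SELENOW (ENSG00000178980, chromosome 19), a selenoprotein, from 135 ± 2.06 to 91.5 ± 2.77 CPM (-0.56 ± 0.05), and TP53INP2 (-0.44). The count of 237 became 89 without Schisandrae high replicate 3, 97 without replicate 1 and 117 without vehicle replicate 1. It was 394 with DESeq2, 488 without the low-count filter and 127 in a fit of the 6 libraries.

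Against vehicle, Longan at the high dose shifted the list of NRF2 targets higher and that of goblet cell genes lower on balance, with most members short of the threshold. It changed 230 genes, 136 higher and 94 lower, of which 2 changed at least 2-fold. SLC7A11 rose by 0.50 ± 0.08 and GCLM by 0.46 ± 0.06, while thioredoxin reductase TXNRD1 rose by 0.20 ± 0.03, from 339 ± 7.20 to 390 ± 18 CPM (adjusted p = 4.1e-04).

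NRF2 targets rose in 9 of 30 cases, and in 12 when adjusted over the list alone, with a median of 0.10 (adjusted p = 1.32e-08, and 1.29e-05 with an estimated correlation). The calls of SLC7A11 and GCLM were lost in a fit of the 6 libraries (0.33 and 0.20), and over 7 alternatives their adjusted p ran from 3.2e-34 to 0.33 and from 4.3e-20 to 0.20. Goblet cell genes fell in 3 of 22 cases, and in 8 when adjusted over the list alone, with a median of -0.15 (adjusted p = 4.11e-06, and 0.000865 with an estimated correlation). Between the high and the low dose of Longan, fry did not call the goblet cell list lower. Aryl hydrocarbon receptor targets rose in 2 of 9 cases, and in 4 when adjusted over the list alone (adjusted p = 0.0018, and 0.0385 with an estimated correlation). The splicing kinase CLK1 rose by 0.45 ± 0.08 and the zinc finger gene ZNF780A by 0.35 ± 0.06, while MT-RNR1 changed by -0.44 ± 0.07. In the same direction, edgeR also called CLK1, ZNF780A and MT-RNR1 at the low dose of Longan (adjusted p = 0.009, 0.0018 and 0.0018). Between the high and the low dose of Longan it called 0 genes. The hormone gene AMH (-0.53), AGR2 (-0.15) and malic enzyme ME1 (0.21) also passed the threshold against vehicle at the high dose. Without Longan high replicate 3 their adjusted p became 0.13, 0.13 and 0.061. The SREBP1 list was called as higher (adjusted p = 0.027, and adjusted p = 0.248 with an estimated correlation) with a median of 0.0254 and a mean of -0.00336. The count of 230 rested on few libraries: it was 9 without Longan high replicate 3, 32 without vehicle replicate 1 and 144 without Longan high replicate 2. It was 483 with DESeq2, 640 without the low-count filter, 101 in a fit of the 6 libraries and 111 after a correction for GC content.

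Zizyphi at the high dose raised inflammatory genes that NF-kB controls. It was the extract for which this list's call was kept with an estimated correlation. The chemokines CCL20, CXCL1 and CXCL8 rose from low levels. More than 0.5 of the NRF2 targets also rose. The lists of endoplasmic reticulum chaperones (higher) and of enterocyte and goblet cell genes (lower) shifted on balance, while most of their members did not pass. It changed 752 genes, 422 higher and 330 lower, of which 19 changed at least 2-fold.

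NF-kB targets rose in 11 of 20 cases (12 rose and 1 fell when adjusted over the list alone), with a median of 0.36 (adjusted p = 3.22e-16, and 2.81e-10 with an estimated correlation). The chemokine CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242) rose by 2.11 ± 0.16, from 1.94 ± 0.288 to 8.44 ± 0.818 CPM, with adjusted p = 1.8e-15. It also rose at the medium dose, by 0.92 ± 0.17 (0.0029). Interleukin 8, CXCL8, rose by 1.20 ± 0.09, from 7.24 ± 0.643 to 16.6 ± 1.90 CPM. The adhesion molecule ICAM1 rose by 0.59 ± 0.12 and mitochondrial superoxide dismutase SOD2 by 0.23 ± 0.04, and outside the list the elastase inhibitor PI3 rose by 1.19 ± 0.12. The chemokine CCL20 rose by 2.99 ± 0.51 but stayed below 1 CPM (0.986 ± 0.263 against 0.116 ± 0.061).

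NRF2 targets rose in 17 of 30 cases (18 rose and 1 fell when adjusted over the list alone), with a median of 0.16 (adjusted p = 3.45e-14, and 7.33e-09 with an estimated correlation). AKR1C2 rose by 0.61 ± 0.07, AKR1B10 by 0.46 ± 0.05 and TXNRD1 by 0.28 ± 0.03. SLC7A11 rose by 0.62 ± 0.08 with adjusted p = 3.4e-06, which was 0.16 in a fit of the 6 libraries and ran from 7.3e-55 to 0.16 over 7 alternatives. Chaperone genes HSP90B1 and HSPA5 rose by 0.17 each and CANX by 0.13, within a list of which 7 of 21 rose and 1 fell (13 and 1 when adjusted over the list alone; adjusted p = 3.6e-08, and 0.00033 with an estimated correlation). Replication genes rose in 9 of 32 cases, and in 16 when adjusted over the list alone, with MCM2 at 0.14 and UHRF1 at 0.16. The ribosome biogenesis genes UTP20 (0.23) and BOP1 (0.24) rose as well.

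Goblet cell genes fell in 8 of 22 cases, and in 10 when adjusted over the list alone, with a median of -0.23 (adjusted p = 9.19e-11, and 3.11e-06 with an estimated correlation). REG4 changed by -0.51 ± 0.06, BCAS1 by -0.37 ± 0.04 and AGR2 by -0.22 ± 0.03. Of 18 enterocyte genes 3 fell, and 4 when adjusted over the list alone, among them LGALS4 (-0.21), with adjusted p = 2.28e-05, and 0.00844 with an estimated correlation. The enterocyte keratin KRT20 did not pass (-0.09, adjusted p = 0.085). The microvillus myosin MYO7B (-0.72 ± 0.13) and the fatty acid hydroxylase CYP4F12 (-0.72 ± 0.16) fell as well. The cholesterol exporter ABCG1 was lower by 0.73 ± 0.16 with adjusted p = 0.0033, which became 0.061 without vehicle replicate 1. The count of 752 became 324 without Zizyphi high replicate 3, 326 without replicate 2 and 347 without vehicle replicate 1, and it was 410 in a fit of the 6 libraries.

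Polygalae at the high dose raised the genes of cholesterol synthesis almost as a block, together with lysosome genes and NRF2 targets. It lowered most genes of mitosis, while the list of goblet cell genes shifted lower on balance, with 10 of 22 members past the threshold. The cholesterol exporter ABCG1 fell. Of 3601 genes called, 1878 were higher and 1723 lower, and 171 changed at least 2-fold. The medium dose already changed 2149 genes.

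Cholesterol synthesis genes and SREBP2 targets rose in 24 of 26 cases by both adjustments, and 0 fell, with a median of 0.64 (adjusted p = 7.18e-35, and 4e-18 with an estimated correlation). Squalene epoxidase SQLE (ENSG00000104549, chromosome 8, 124998497 to 125022283) rose by 0.61 ± 0.02, from 663 ± 7.63 to 1010 ± 0.390 CPM, with adjusted p = 3.8e-30. IDI1 rose by 0.81 ± 0.04, INSIG1 by 0.72 ± 0.03 and HMGCS1, which acts early in the pathway, by 0.70 ± 0.03. The list of fatty acid synthesis and SREBP1 targets rose in 8 of 12 cases and fell in 1 by both adjustments (adjusted p = 1.13e-22, and 3.47e-08 with an estimated correlation). Its members included acetyl-CoA synthetase ACSS2 at 1.43 ± 0.06 and the desaturase SCD at 0.45 ± 0.03. TMEM97, which was counted in that list but is no enzyme of fatty acid synthesis, rose by 0.42 ± 0.04. ABCG1 (ENSG00000160179, chromosome 21) fell from 2.66 ± 0.480 to 1.06 ± 0.102 CPM, a log2 fold change of -1.31 ± 0.18.

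Lysosome and autophagy genes rose in 27 of 32 cases and fell in 1, and 29 rose and 1 fell when adjusted over the list alone, with a median of 0.32 (adjusted p = 1.34e-28, and 2.38e-12 with an estimated correlation). The autophagy receptor SQSTM1 (ENSG00000161011, chromosome 5, 179806398 to 179838078) rose by 1.39 ± 0.03, from 348 ± 11.1 to 910 ± 14 CPM, with adjusted p = 1.1e-46. Sialidase NEU1 rose by 1.07 ± 0.04 and folliculin FLCN, which regulates lysosomal signalling, by 1.06 ± 0.06. NRF2 targets rose in 23 of 30 cases and fell in 1 (26 and 1 when adjusted over the list alone), with a median of 0.38 (adjusted p = 1.39e-24, and 3.34e-10 with an estimated correlation). OSGIN1 rose by 1.29, HMOX1 by 0.94, SLC7A11 by 0.85, ferritin heavy chain FTH1 by 0.71, GCLM by 0.69 and TXNRD1 by 0.59. The stress genes CDKN1A (0.85), GDF15 (0.93) and DDIT3 (0.83) rose too.

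Large rises included those of UAP1L1 (2.00 ± 0.09), SQSTM1, ACSS2, the protein kinase A inhibitor PKIB (1.37 ± 0.07) and the long non-coding RNA UCA1 (1.3 ± 0.08). ICAM1 rose by 1.20 and the phosphatase DUSP5 by 1.12. Goblet cell genes fell in 10 of 22 cases and rose in 1 (11 and 2 when adjusted over the list alone), with a median of -0.35 (adjusted p = 4.16e-14, and 0.000262 with an estimated correlation). The gel-forming mucin MUC5AC (ENSG00000215182, chromosome 11) changed by -1.12 ± 0.10, from 299 ± 16.6 to 138 ± 18.3 CPM, MUC2 by -0.81 ± 0.17, the lineage factor SPDEF by -0.53 ± 0.06 and AGR2 by -0.40 ± 0.03. The colon antigen GPA33 (-0.99), SPEG (-0.95), the vitamin B12 binder TCN1 (-0.93) and villin VIL1 (-0.55) fell. Mitosis genes fell in 22 of 32 cases and rose in 1 (23 and 1 when adjusted over the list alone), with a median of -0.17 against -0.80 with wortmannin (adjusted p = 7.94e-15, and 0.000241 with an estimated correlation). KIF20A changed by -0.33 and NUSAP1 by -0.26. The count of 3601 became 2141 in a fit of the 6 libraries.

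Aucklandiae at the high dose raised all 30 tested NRF2 targets, the widest response of that list in these comparisons. Aldo-keto reductases led it. The list of enzymes and transporters for foreign compounds shifted higher on balance, with 9 of 20 members past the threshold and 4 the other way. Most goblet cell and WNT target genes fell, and the list of FOXO targets shifted lower on balance. Of 3389 genes called, 1833 were higher and 1556 lower, and 117 changed at least 2-fold.

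All 30 NRF2 targets rose by both adjustments, with a median of 0.69 (adjusted p = 8.83e-38, and 1.7e-23 with an estimated correlation). AKR1C2 rose by 2.65 ± 0.06, from 16.8 ± 1.36 to 106 ± 4.24 CPM, with adjusted p = 7.4e-43. AKR1C1 rose by 2.13 ± 0.06, AKR1B10 by 1.87 ± 0.05 and AKR1C3 by 1.79 ± 0.10. SLC7A11 (ENSG00000151012, chromosome 4) rose by 1.23 ± 0.08, to 288 ± 23.5 CPM. GCLM rose by 1.07, the ferritin light chain FTL by 0.93, NQO1 by 0.89, ME1 by 0.65 and HMOX1 by 0.64. Aryl hydrocarbon receptor targets rose in 4 of 9 cases, and in 5 when adjusted over the list alone (adjusted p = 9.08e-19, and 2.07e-07 with an estimated correlation), ALDH3A1 by 1.68 ± 0.05. Of 20 xenobiotic genes 9 rose and 4 fell (10 and 4 when adjusted over the list alone), with the efflux pump ABCG2 at 0.79 ± 0.03, UGT1A6 at 0.78 ± 0.06 and UGT1A10 at 0.51 ± 0.03.

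ATF4 targets rose in 11 of 29 cases and fell in 2 (11 and 3 when adjusted over the list alone), among them SLC3A2 (0.51), PSAT1 (0.30) and ASNS (0.24), in the direction opposite to wortmannin. Chaperone genes of the endoplasmic reticulum rose in 12 of 21 cases (13 rose and 1 fell when adjusted over the list alone), and glycolysis genes in 13 of 18 by both adjustments, including the lactate exporter SLC16A3 (0.45), HK2 (0.35) and PFKP (0.34). Cholesterol synthesis genes rose in 13 of 26 cases and fell in 2 (15 and 2 when adjusted over the list alone), with a median of 0.12 (adjusted p = 7.83e-10, and 0.00879 with an estimated correlation). CYP51A1 rose by 0.26 and SQLE by 0.17. In the lysosome list SQSTM1 rose by 0.45 and the galactosidase GLA by 0.54.

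Goblet cell genes fell in 13 of 22 cases by both adjustments, with a median of -0.40 (adjusted p = 5.92e-17, and 2.67e-06 with an estimated correlation). REG4 (ENSG00000134193, chromosome 1, 119794018 to 119811660) changed by -1 ± 0.06, from 23.4 ± 1.32 to 11.7 ± 0.670 CPM, MUC2 by -0.82 ± 0.16, BCAS1 by -0.43 ± 0.04 and MUC13 by -0.41 ± 0.04. Large falls outside the list included those of CD200 (-1.19 ± 0.14), the Notch ligand DLL4 (-1.04 ± 0.16) and RASL11A (-1.02 ± 0.07). FOXO targets fell in 10 of 21 cases and rose in 1 (12 and 1 when adjusted over the list alone), TXNIP by 0.61 and SESN1 by 0.38 on the log2 scale. WNT targets fell in 11 of 20 cases and rose in 1 (12 and 1 when adjusted over the list alone), including EPHB3 (-0.44) and PROX1 (-0.45). The YAP target CCN2 changed by -0.69 ± 0.14. In 3 lists the median and the mean had different signs: SREBP1 (called higher, 0.0229 and -0.00953), hypoxia (called higher, 0.0833 and -0.0651) and fatty acid oxidation (called lower, 0.0176 and -0.0919). None of these 3 calls was kept: adjusted p = 0.118, 0.278 and 0.24 with an estimated correlation.

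**Figure D2:**
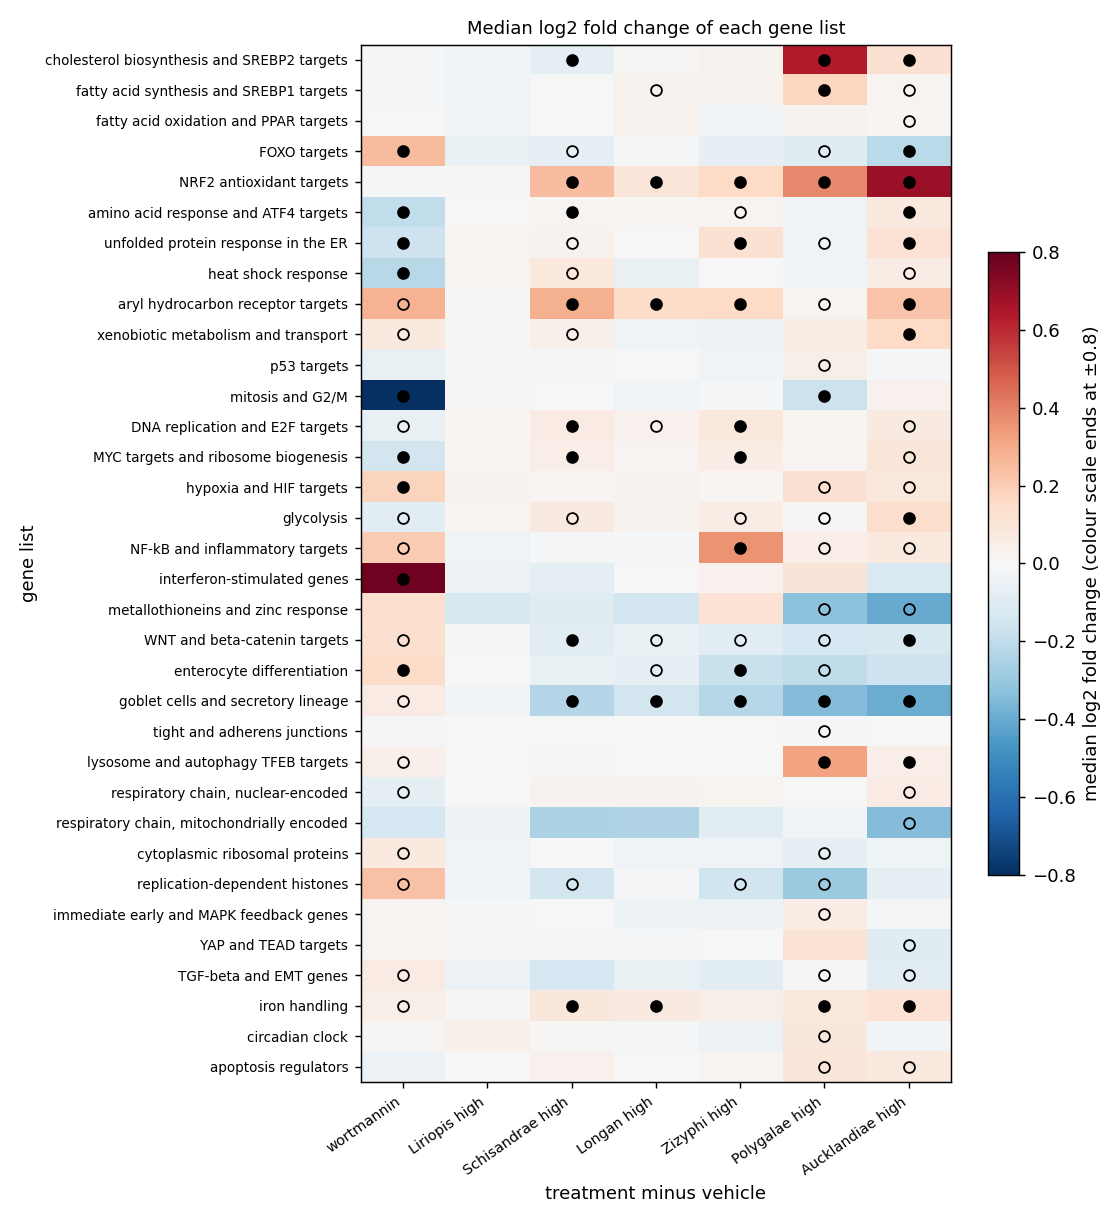
Median log2 fold change (colour) of the 34 tested gene lists (y axis) for wortmannin and the high dose of each extract minus vehicle (x axis). A circle marks a call by fry, and a filled circle marks a call kept with an estimated correlation; the Liriopis column has 0 circles.

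At the medium dose the responses of the active extracts were partly present. At the low dose SQSTM1 with Polygalae was 362 to 363 CPM, against 337 to 359 in vehicle. AKR1C2 with Aucklandiae was 18.4 to 21.5 against 15.8 to 18.4 CPM, and CXCL1 with Zizyphi 2.39 to 3.01 against 1.64 to 2.21 CPM. Polygalae at the medium dose raised UAP1L1 by 1.78 ± 0.09, PKIB by 1.29 ± 0.07 and the amino acid transporter SLC6A20 by 1.18 ± 0.09, and lowered MUC5AC by 0.88 ± 0.10 and ABCG1 by 0.94 ± 0.16 on the log2 scale. Aucklandiae at the medium dose changed 599 genes, with AKR1C2 (0.72 ± 0.07) and AKR1C3 (0.67 ± 0.10) among the largest rises. That count became 247 without vehicle replicate 1, 351 without vehicle replicate 2, 391 without Aucklandiae medium replicate 2, 278 without replicate 3 and 205 in a fit of the 6 libraries. Zizyphi at the medium dose raised PI3 by 0.73 ± 0.12 among 206 genes. That count was 27 without vehicle replicate 1, 96 without vehicle replicate 2, and 43, 19 and 121 without Zizyphi medium replicates 1, 2 and 3. It was 394 with DESeq2 and 504 without the low-count filter.

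Schisandrae at the medium dose changed 38 genes, among them the RAS-related GTPase MRAS by -0.46 ± 0.10 with adjusted p = 0.03, from 0.0041 to 0.085 (in a fit of the 6 libraries) over 6 alternatives. For MRAS that p was 0.089 without vehicle replicate 1, 0.11 without vehicle replicate 2, 0.072 without Schisandrae medium replicate 2 and 0.32 without replicate 3. The count of 38 was 14, 25 and 88 without vehicle replicates 1, 2 and 3. It was 128, 7 and 2 without Schisandrae medium replicates 1, 2 and 3. It was 171 with DESeq2, 370 without the low-count filter, 112 with a replicate block, 21 in a fit of the 6 libraries and 85 after a correction for GC content. Longan at the medium dose changed MT-RNR1 (-0.44 ± 0.07), a call that was lost without Longan medium replicate 2 (0.073), while 3 genes were called without vehicle replicate 2, 7 without vehicle replicate 3 and 2 without Longan medium replicate 3. DESeq2 called 43 there, and 249 were called without the low-count filter, 11 with a replicate block, 26 in a fit of the 6 libraries and 10 after GC correction.

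At the low dose the same genes recurred across extracts, which the use of the same 3 vehicle libraries in each comparison can produce without any extract effect. Counts were 73 for Longan, 51 for Zizyphi, 91 for Polygalae and 227 for Aucklandiae, while Schisandrae had 0 (1392 at an unadjusted p under 0.05 by edgeR, and 19 by DESeq2). CLK1 (ENSG00000013441, chromosome 2) was higher by 0.58 ± 0.08 with Polygalae and by 0.56 ± 0.08 with Aucklandiae, against 32.4 ± 1.35 CPM in vehicle. Its relative CLK4 was higher by 0.51 ± 0.09 with Aucklandiae. MT-RNR1 was lower by 0.48 ± 0.07 with Zizyphi, 0.46 ± 0.07 with Polygalae and 0.49 ± 0.07 with Aucklandiae on the log2 scale. These counts moved strongly with the vehicle libraries. Without vehicle replicate 1 they were 2 (Longan), 1 (Zizyphi), 7 (Polygalae) and 11 (Aucklandiae), and without vehicle replicate 2 they were 35, 16, 36 and 99. Without vehicle replicate 3 Longan had 119. Without replicates 1, 2 and 3 of the treated group, Zizyphi had 18, 5 and 8, Polygalae 49, 10 and 46, and Aucklandiae 83, 27 and 118, and Longan had 7 without replicate 2 and 0 without replicate 3. DESeq2 called 248 (Longan), 161 (Zizyphi), 309 (Polygalae) and 558 (Aucklandiae) genes, and after a correction for GC content Longan had 42. Without the low-count filter 441, 383, 478 and 687 were called, and 195 for Schisandrae. A fit of the 6 libraries called 129 for Zizyphi, 393 for Aucklandiae and 8 for Schisandrae. A replicate block gave 341 for Aucklandiae and 7 for Schisandrae, which had 2 after GC correction.

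**Figure D3:**
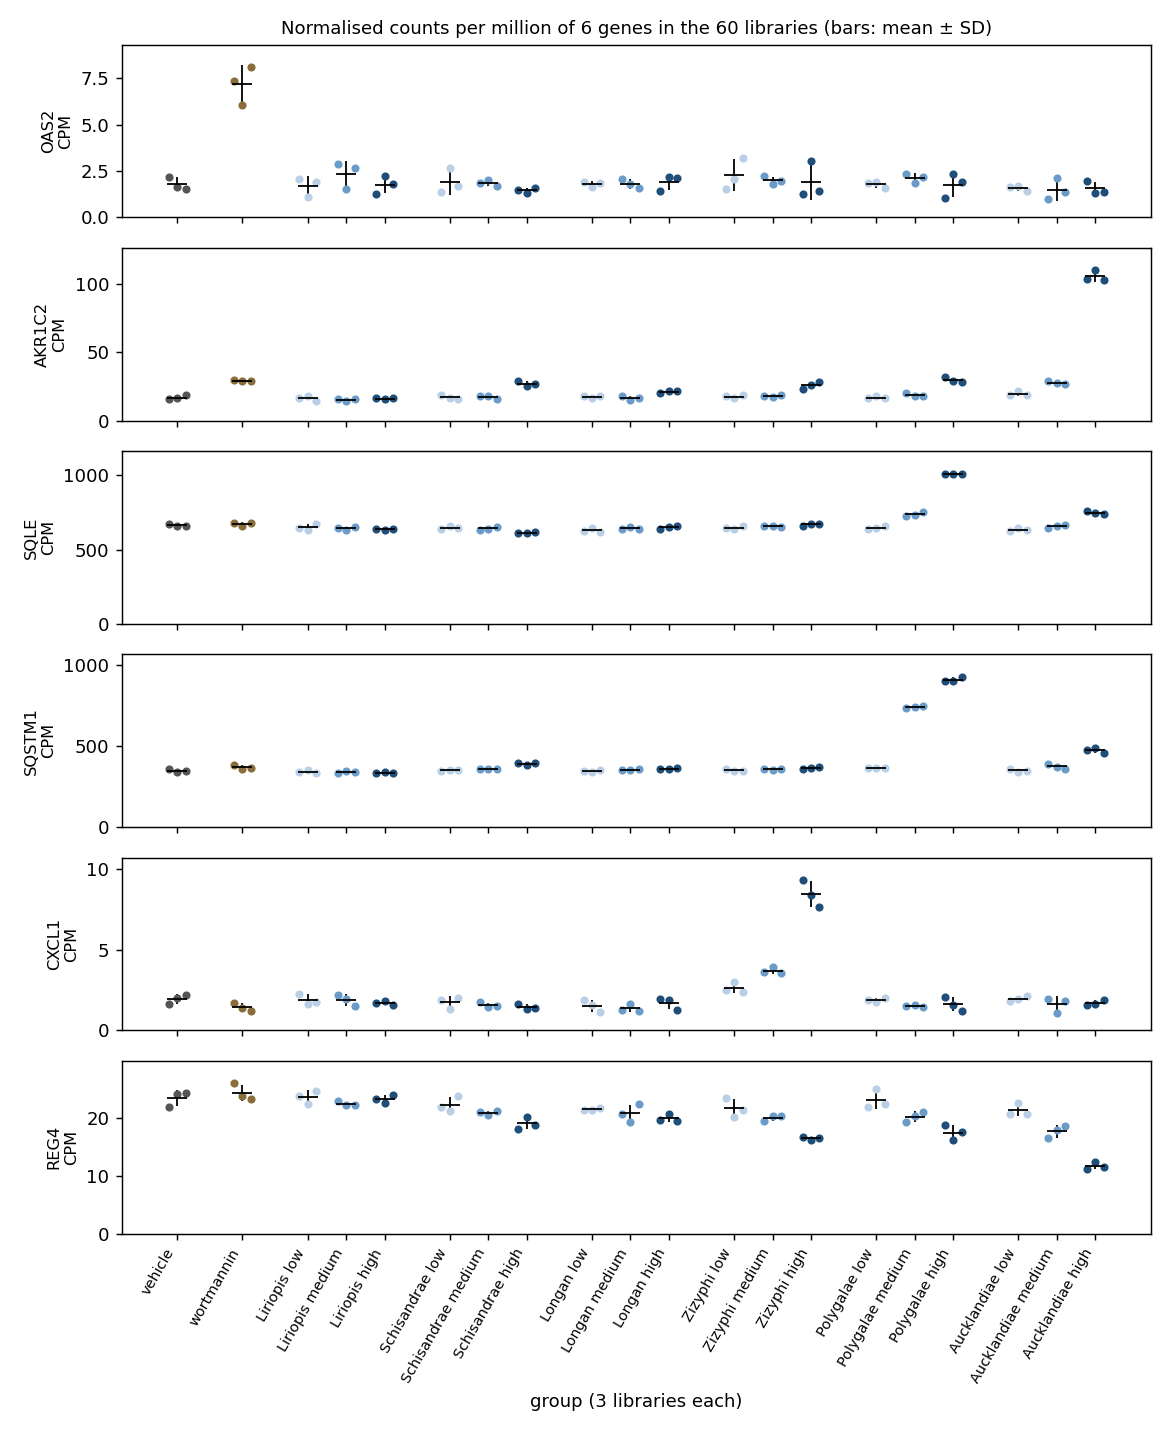
Normalised CPM (y axis, from 0) of 6 genes in the 3 libraries of each of the 20 groups (x axis); points are libraries and bars the mean ± SD. OAS2 stands out with wortmannin (7.16 CPM), AKR1C2 with the high dose of Aucklandiae (106 CPM), SQLE and SQSTM1 with that of Polygalae and CXCL1 with that of Zizyphi (8.44 CPM).

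Comparing the high with the low dose asked what each extract changed within its own library set. Cholesterol and lysosome genes rose again with Polygalae, NRF2 targets with Aucklandiae and chemokines with Zizyphi. Polygalae changed 2893 genes (1521 higher, 1372 lower), Aucklandiae 1860 (1060 higher, 800 lower), Zizyphi 70, Schisandrae 50, and Liriopis and Longan 0 each. For those counts of 0 from edgeR, 913 and 629 genes had an unadjusted p under 0.05, and DESeq2 called 1 and 3. Without the low-count filter they were 195 and 109, and for Longan 2 in a fit of the 6 libraries and 2 after GC correction. The count for Liriopis became 1 without Liriopis low replicate 1 or 3 or without Liriopis high replicate 2, and that for Longan became 1 without Longan high replicate 1.

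With Polygalae, 24 of 26 cholesterol synthesis genes rose by both adjustments, with a median of 0.62 (adjusted p = 7.04e-35, and 4.58e-19 with an estimated correlation). Lysosome genes rose in 25 of 32 cases and fell in 1 (28 and 1 when adjusted over the list alone), with a median of 0.32. UAP1L1 rose by 1.95 ± 0.09, ACSS2 by 1.57 ± 0.06 and SQSTM1 by 1.33 ± 0.03. ABCG1 changed by -1.21 ± 0.18, ATOH1, which commits cells to the secretory fate, by -0.96 ± 0.17 and NEB by -0.94 ± 0.15. The Polygalae count of 2893 was 1750 in a fit of the 6 libraries.

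With Aucklandiae all 30 NRF2 targets rose by both adjustments, with a median of 0.65 (adjusted p = 4.82e-37, and 1.97e-25 with an estimated correlation). AKR1C2 rose by 2.44 ± 0.06, AKR1C1 by 1.96 ± 0.06 and AKR1B10 by 1.74 ± 0.05, while CD200 changed by -1.27 ± 0.14 and RASL11A by -1.07 ± 0.07. In the p53 list the test pointed down (adjusted p = 0.00734, and adjusted p = 0.237 with an estimated correlation) with a median of 0.0185 and a mean of -0.0543. In the hypoxia list it pointed up (adjusted p = 0.00244, and adjusted p = 0.237 with an estimated correlation) with a median of 0.0789 and a mean of -0.0252.

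With Zizyphi 6 of 20 NF-kB targets rose, and 9 when adjusted over the list alone, with a median of 0.24 (adjusted p = 1.9e-13, and 2.05e-11 with an estimated correlation). CXCL1 rose by 1.67 ± 0.15, CXCL8 by 1.20 ± 0.09 and PI3 by 1.04 ± 0.11. The count of 70 was 37, 30 and 40 without Zizyphi high replicates 1, 2 and 3 and 34, 28 and 39 without Zizyphi low replicates 1, 2 and 3. It was 202 without the low-count filter.

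With Schisandrae 16 of 30 NRF2 targets rose, and 25 when adjusted over the list alone, with a median of 0.19 (adjusted p = 1.77e-17, and 9.58e-16 with an estimated correlation). AKR1C2 rose by 0.66 ± 0.07 and HMOX1 by 0.56 ± 0.07, and SELENOW changed by -0.46 ± 0.05, from 126 ± 5.23 to 91.5 ± 2.77 CPM. The count of 50 was 30 without Schisandrae high replicate 1, 32 without Schisandrae low replicate 2, 83 with DESeq2 and 199 without the low-count filter. With Longan no single NRF2 target passed over all genes, 12 rose when adjusted over the list alone, and the median of the list was 0.08 (adjusted p = 5.51e-05, and 1.42e-05 with an estimated correlation). Among the extracts NRF2 targets rose as a list in 5 of 6, and fry did not call them for Liriopis. For Zizyphi the marker genes of that list were mixed within its set. By edgeR GCLM (0.26, adjusted p = 0.018) and SLC7A11 (0.34, 0.045) passed. AKR1C1 (0.25, 0.11), HMOX1 (0.22, 0.29) and NQO1 (0.12, 0.071) did not. For Longan fry called 3 lists here, 3 higher and 0 lower. The fall of its goblet cell list against vehicle was therefore not called within its set.

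**Figure D4:**
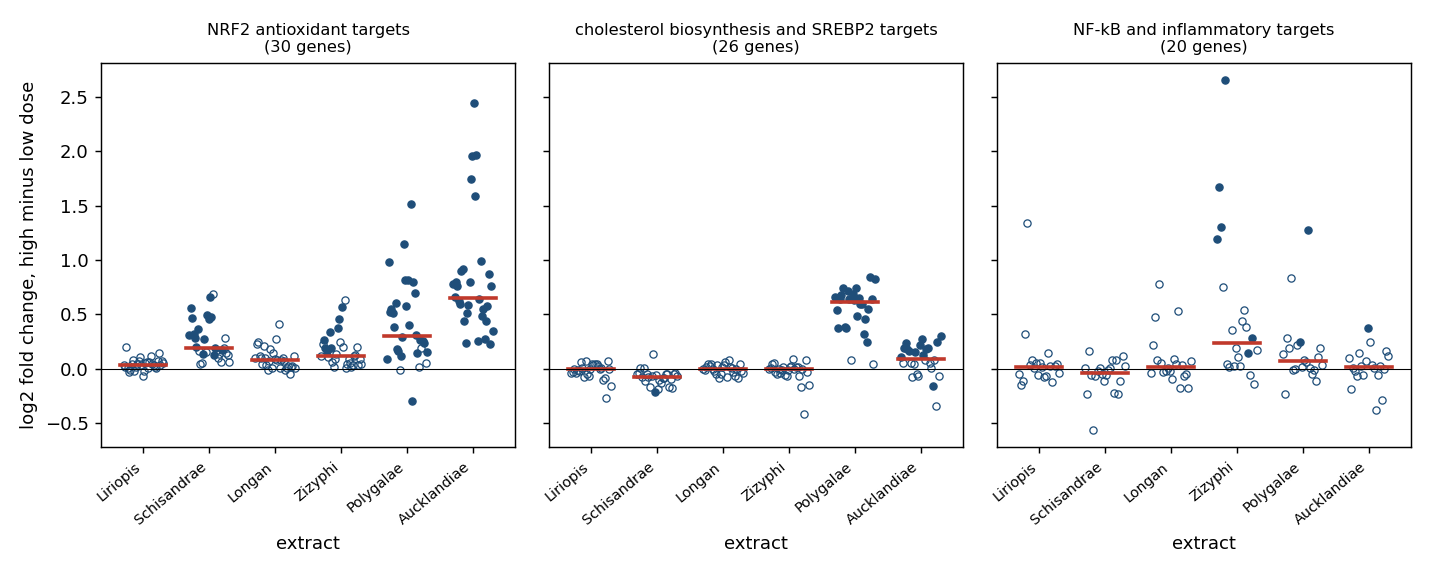
Log2 fold change of the high minus the low dose (y axis) of each gene of 3 lists in the 6 extracts (x axis). Filled points have an adjusted p under 0.05 and red lines are medians: 0.65 for NRF2 targets with Aucklandiae, 0.62 for cholesterol genes with Polygalae and 0.24 for NF-kB targets with Zizyphi.

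A test of the difference itself asked whether the change from the low to the high dose was equal in the 6 extracts, and 1716 of 16729 genes (10.3%) differed. Among 39 tested genes fixed beforehand as markers of known pathways, 24 differed. SQSTM1 differed with adjusted p = 7.2e-39, rising by 1.33 with Polygalae, 0.44 with Aucklandiae and 0.16 with Schisandrae. AKR1C1 differed with adjusted p = 4.2e-27 and NQO1 with 2.8e-22, both highest with Aucklandiae (1.96 and 0.78). HMGCS1 (9.6e-21) rose by 0.66 with Polygalae and 0.11 with Aucklandiae, and SCD (2.1e-18) rose by 0.48 with Polygalae and fell by 0.16 with Zizyphi. CXCL8 (5.5e-12) rose with Zizyphi, and ASNS (5.3e-09) rose by 0.20 with Aucklandiae and fell by 0.33 with Polygalae.

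Across genes, which are not independent replicates, the responses of Polygalae and Aucklandiae overlapped. For high minus low dose, 356 genes were called higher in both against 96.4 expected from independent calls. Another 312 were lower in both against 65.6, and 110 opposite against 160. The expected numbers, also those for wortmannin below, take every tested gene as equally likely to be called. In the simulation, genes of at least 10 CPM were recovered more often, so the expected numbers can be too low. The shared rises included SQSTM1, HMOX1 and GCLM, and the shared falls TXNIP and CA9. Pearson's r of their log2 fold changes was 0.14 over 16729 genes and 0.34 over the 5951 genes with a mean of at least 5 log2 CPM. Several extracts moved genes against the direction of wortmannin: 973 opposite against 304 expected for Aucklandiae, TXNIP and ASNS among them, 935 against 472 for Polygalae (with 241 higher in both against 239 and 266 lower in both against 231), 36 against 11.5 for Zizyphi and 16 against 8.25 for Schisandrae (7 higher in both against 5.51, and 4 lower in both against 2.52). Zizyphi had 5 higher in both against 6.3 and 3 lower against 5.05, and Aucklandiae 120 against 167 and 48 against 135. For Aucklandiae and wortmannin r was -0.0935, or -0.282 over the 5951 genes. The 21 pairs compared are a description, without a p-value.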

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

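The test of equal high-minus-low changes was planned before the data were seen. The explanations weighed below, and the splits of libraries, were chosen after results had been seen.

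The change from the low to the high dose differed between extracts in 1716 genes, and a difference between groups is what brought these results here. Among the marker genes fixed beforehand, 24 differed. Large differences were those of SQSTM1 (adjusted p = 7.2e-39), AKR1C1 (4.2e-27), NQO1 (2.8e-22), HMGCS1 (9.6e-21), SCD (2.1e-18), TXNIP (3.2e-13), CXCL8 (5.5e-12), CDKN1A (3.8e-10), HMOX1 (3.9e-10), TRIB3 (7.3e-10), CA9 (3.8e-09) and ASNS (5.3e-09). Further differences were those of CEACAM6 (8.4e-08), GCLM (4.5e-07), KRT20 (1.1e-06), SLC7A11 (3.4e-06), GDF15 (1.2e-05), DDIT3 (3.9e-05), HSPA5 (0.00087), CCND1 (0.0028), IRS2 (0.0029), ABCB1 (0.02) and CCL20 (0.04). TXNIP fell with Polygalae (-0.65) and Aucklandiae (-0.57), and CDKN1A rose most with Polygalae (0.81). When the 36 high- and low-dose libraries were regrouped at random within extracts, the true grouping called 1543 genes and 1 of 30 splits, the true one, reached that number. The highest other split called 783. Such regrouping removes any effect of dose, so a strong dose effect in 1 extract is enough to set the true grouping apart. It therefore cannot show whether the changes differ between extracts.

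SREBP2 targets rose with Polygalae while the sterol exporter ABCG1 fell. A GC trend between libraries is argued against: after GC correction the median was 0.621, which is 97.5% of 0.637. A single library that stands apart is argued against too, since the lowest median without 1 Polygalae high library was 0.613, or 96.3%. Less sterol for the liver X receptor, which drives ABCG1, would lower its other targets: their median was 0.0401 over 9 genes, with SMPDL3A (0.61) higher and MYLIP (-0.25) and LPCAT3 (-0.23) lower. A median over 0 had been set as against it, but the genes split both ways and the fall of ABCG1 and 1 of the 9 values had been seen before that was written, so it is left open.

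NF-kB targets rose with Zizyphi. White blood cells in the cultures would bring their own transcripts, but the summed change of 5 of them was -3.78% of the rise of CXCL8, with CD74 at 3.37 ± 0.545 CPM against 3.73 ± 0.373 in vehicle. Without 1 Zizyphi high library the median of the list was at least 0.328, or 90.8% of 0.361. A bacterial product in the extract and a plant compound acting on the cells both stay open, since no table here separates them.

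At the low dose of 4 extracts, 442 gene calls included CLK1 and MT-RNR1 repeatedly, against the same 3 vehicle libraries. After GC correction 71.3% of these calls were kept, while the median difference from vehicle went from 0.202 to 0.182. The bounds written beforehand, under 50% for a GC trend and over 80% against it, were for the 4 extracts together and the value lay between them. Single extracts ran from 41.1% (Longan) over 71.8% (Aucklandiae) and 85.7% (Polygalae) to 86.3% (Zizyphi). The higher genes had a median GC content of 41.1% against 56.8% for the lower ones, and how far a GC trend accounts for these calls is left open. Measured against the low doses of the other sets, the median difference was 37.2% of that against vehicle, which leaves open whether the vehicle libraries stand apart. Whether they would do so by their set or by their solvent was not tested. From the medium to the high dose the same genes moved by 6.53% of that difference. The prediction written beforehand took under 10% as against an effect that grows with dose, and the value of the 4 extracts together met that bound. No single extract reached the higher bound written for such an effect. Since single extracts ran from -14.7% to 17.1%, on both sides of 10%, the matter is left open.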

How the results depend on the processing

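All alternatives but the GC correction were chosen before the data were examined. The counts for wortmannin, for the medium and high doses of Polygalae, for the high dose of Aucklandiae and for high minus low of both stayed within 1.5 times their value when any 1 library was left out (4487 to 5049 for wortmannin, 2779 to 3609 for Polygalae high, 2582 to 2840 for Aucklandiae high). The 1716 genes that differed between extracts became 1810 with a replicate block, 1712 with RLE scaling, 2374 without the low-count filter, 1543 in the 36 libraries alone and 2009 after GC correction.

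Leaving out 1 library gave 1 to 4 genes for Liriopis low, 0 to 1 for Liriopis medium and 0 to 5 for Liriopis high. For Schisandrae the ranges were 0 to 4 (low), 2 to 128 (medium) and 89 to 325 (high), for Longan 0 to 119, 0 to 7 and 9 to 302, and for Zizyphi 1 to 64, 19 to 189 and 324 to 805. They were 7 to 93 for Polygalae low, 11 to 260 for Aucklandiae low and 247 to 444 for Aucklandiae medium. For high minus low they were 0 to 1 (Liriopis), 30 to 47 (Schisandrae), 0 to 1 (Longan) and 28 to 40 (Zizyphi).

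DESeq2 called 12, 2 and 26 genes for the low, medium and high dose of Liriopis, 19, 171 and 394 for Schisandrae, 248, 43 and 483 for Longan, 161 and 394 for the low and medium dose of Zizyphi, 309 for Polygalae low and 558 for Aucklandiae low. For high minus low it called 1 (Liriopis), 83 (Schisandrae) and 3 (Longan). The cause was not tested.

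Without the low-count filter, in the same order, the counts were 286, 157 and 158 (Liriopis), 195, 370 and 488 (Schisandrae), 441, 249 and 640 (Longan), 383 and 504 (Zizyphi low and medium), 478 (Polygalae low) and 687 (Aucklandiae low). For high minus low they were 195 (Liriopis), 199 (Schisandrae), 109 (Longan) and 202 (Zizyphi). The cause was not tested.

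In a fit of only the 2 groups compared the counts were 21, 4 and 3 (Liriopis), 8, 21 and 127 (Schisandrae), 26 and 101 (Longan medium and high), 129 and 410 (Zizyphi low and high), 2141 (Polygalae high) and 393 and 205 (Aucklandiae low and medium). For high minus low they were 2 (Longan) and 1750 (Polygalae). Some counts rose and others fell, and the cause was not tested.

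With a replicate block the counts were 7, 8 and 16 (Liriopis), 7 and 112 (Schisandrae low and medium), 11 (Longan medium) and 341 (Aucklandiae low), and the block moved no other count by over 1.5 times. The replicate numbers were not taken to pair the samples, since the sources tie no culture or day to them and 4 of 570 pairs of the same number had a correlation over 0.1. The mean was 0.00655 (-0.106 to 0.108). Still, 32 of 60 libraries correlated best with their own number, where numbers shuffled within groups gave 20.1 on average and reached 32 with p = 0.0145 (0.002 for the mean correlation). This shuffle was added after the results had been seen. It is a hint from the data of a small shared effect, whose origin is not given in the sources used here. The block changed no call of a named gene and 1 of 186 list calls.

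After GC correction the counts were 2 and 1 (Liriopis low and high), 2 and 85 (Schisandrae low and medium), 42, 10 and 111 (Longan), and 2 (Longan high minus low). RLE scaling gave 2 for Liriopis low. Counts that were not rounded moved none of these results by over 1.5 times.

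With a 2-fold minimum, which by construction keeps fewer genes, 194 remained for wortmannin, 0 for Liriopis low and 0 for Liriopis medium, 1 and 3 for Schisandrae medium and high, 3, 0 and 2 for Longan, 3, 3 and 19 for Zizyphi, 2, 54 and 171 for Polygalae and 2, 11 and 117 for Aucklandiae. For high minus low 0 (Schisandrae), 6 (Zizyphi), 139 (Polygalae) and 68 (Aucklandiae) remained.

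With camera, which both compares a list with the other genes and estimates the correlation, list calls went from 22 to 9 (wortmannin), 15 to 9 (Schisandrae), 8 to 4 (Longan), 24 to 7 (Polygalae) and 25 to 12 (Aucklandiae), and for high minus low from 28 to 7 (Polygalae) and 24 to 12 (Aucklandiae). No alternative changed 1 of these 2 things alone, so the cause of the drop was not tested. Of 186 list calls camera kept 91, and 185 were kept with the block, 183 with RLE scaling and 183 after GC correction, and none reversed under these.

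Of 451 results of named genes, 67 lost their call in a fit of only the 2 groups, 19 after GC correction, 17 without the filter, 2 without rounding and 1 with RLE scaling. DESeq2 gave an adjusted p for 417, of which 6 lost their call. Leaving out 1 library ended the call of 110, and none reversed under any of these.

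Over the 5951 genes with at least 5 log2 CPM, which measures fewer genes with more counts, Pearson's r between high-minus-low responses changed sign in 5 pairs. It went from -0.0822 to 0.104 (Liriopis and Polygalae), from 0.012 to -0.159 (Liriopis and wortmannin), from -0.0351 to 0.164 (Schisandrae and Zizyphi), from -0.0348 to 0.233 (Zizyphi and Polygalae) and from -0.0126 to 0.381 (Zizyphi and Aucklandiae). With Liriopis it became 0.155 (Longan), 0.2 (Zizyphi) and 0.244 (Aucklandiae). With Schisandrae it became 0.161 (Longan), 0.368 (Aucklandiae) and -0.225 (wortmannin). With Longan it became 0.233 (Zizyphi), 0.21 (Polygalae) and 0.248 (Aucklandiae). It became -0.27 for Zizyphi and wortmannin, 0.34 for Polygalae and Aucklandiae and -0.282 for Aucklandiae and wortmannin. In the 5 pairs where Pearson's r changed sign, Spearman's correlation of ranks kept its sign between the same 2 gene sets. It was 0.0205 and 0.102 (Liriopis and Polygalae), -0.075 and -0.166 (Liriopis and wortmannin) and 0.0996 and 0.176 (Schisandrae and Zizyphi). For Zizyphi it was 0.112 and 0.229 with Polygalae and 0.182 and 0.331 with Aucklandiae.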

Other observations

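The splits of libraries given here were chosen after results had been seen, and the gene lists before.

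Several lists outside the main descriptions moved as well. With wortmannin 16 of 43 cytoplasmic ribosomal protein genes rose and 1 fell, by both adjustments, RPL3 by 0.18 (list adjusted p = 0.0168, and adjusted p = 0.616 with an estimated correlation), and 14 of 37 nuclear-encoded respiratory chain genes fell by both adjustments, NDUFA6 by 0.31 on the log2 scale (0.0014, and adjusted p = 0.526 with an estimated correlation). With Aucklandiae 7 of 13 mitochondrially encoded respiratory chain genes fell, and 11 when adjusted over the list alone, MT-ND4L by 0.34 on the log2 scale (0.00584, and adjusted p = 0.31 with an estimated correlation). The mitochondrial share of counts was 10.1% in vehicle and lower in all 18 extract groups, 7.97% at the high and 8.33% at the low dose of Aucklandiae, and between those doses the list was not called (adjusted p = 0.634). With Polygalae the clock genes BHLHE40 (1.09) and NR1D2 (0.23) rose, in a list with 6 rises and 3 falls among 16 (7 and 3 when adjusted over the list alone; 0.000103, and adjusted p = 0.277 with an estimated correlation). Metallothionein genes MT1E (-0.35) and MT2A (-0.39) fell with Aucklandiae, in a list of 7 with adjusted p = 1.03e-05, and adjusted p = 0.0805 with an estimated correlation.

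Means of transcripts of other cell types were 5.85 CPM for CD68, 3.09 for CD14 and 1.84 for ITGAM of leukocytes. The highest of the lists other than liver were 1.56 CPM for COL1A1 of fibroblasts, 1.2 CPM for PECAM1 of endothelium, 0.504 CPM for NAPSA of lung epithelium and 4.17 CPM for TUBB3 of neurons. Lysozyme (LYZ, 1520 CPM) and the liver-enriched SERPINA1 (300 CPM) and HNF4A (85.9 CPM) are genes that intestinal cells also express. HNF4A was lower with Polygalae (-0.26, adjusted p = 3.4e-08), Aucklandiae (-0.20, 9.43e-06) and Schisandrae (-0.17, 0.00207). SERPINA1 was lower with Aucklandiae (-0.31, 2.21e-08), Polygalae (-0.18, 4e-04), Schisandrae (-0.17, 0.0101) and Zizyphi (-0.16, 0.0131). With wortmannin LYZ (0.48, 6.4e-20), CD14 (0.46, 0.0182), NAPSA (0.85, 0.0371) and TUBB3 (0.37, 0.0111) were higher. ITGAM was higher with Aucklandiae (0.62, 0.0162), and TEK (-0.82, 0.0405) and LYZ (-0.15, 0.000184) were lower with Polygalae.

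The 3 and 3 libraries of each comparison, fitted alone, were also divided in all 10 ways, which are too few for a share under 0.05. For the true grouping and the highest other one the calls were 4993 and 0 for wortmannin. At the high dose they were 2141 and 1 (Polygalae), 2788 and 1 (Aucklandiae), 410 and 2 (Zizyphi), 127 and 4 (Schisandrae), 101 and 2 (Longan) and 3 and 6 (Liriopis, where 4 of 10 splits called at least 3). At the medium dose they were 2253 and 1 (Polygalae), 205 and 4 (Aucklandiae), 190 and 4 (Zizyphi), 21 and 3 (Schisandrae), 26 and 3 (Longan) and 4 and 6 (Liriopis, 2 of 10). At the low dose they were 103 and 2 (Polygalae), 393 and 2 (Aucklandiae), 129 and 7 (Zizyphi), 8 and 4 (Schisandrae), 84 and 4 (Longan) and 21 and 3 (Liriopis). For high minus low they were 1750 and 1 (Polygalae), 1660 and 1 (Aucklandiae), 57 and 7 (Zizyphi), 51 and 10 (Schisandrae), 2 and 7 (Longan, 5 of 10) and 0 and 15 (Liriopis, 10 of 10). Where no other number is given, 1 of 10 splits, the true one, reached its count.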
